A study of Homo sapiens with 15 samples.

How the data were processed

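Gene expression was measured in IMR-90 cells, an established line of human lung fibroblasts, with 15 Affymetrix PrimeView oligonucleotide arrays, 1 array per sample. Per the labels' protocols, cells received TGFβ1 at 2 ng/ml and were transfected with pools of siRNA against YAP, TAZ or both, or with a non-targeting pool, for 72 hours, and biotin-labelled cRNA was made from total RNA. The arrays fell into 5 groups of 3: control, TGFβ1 with non-targeting siRNA, TGFβ1 with TAZ siRNA, TGFβ1 with YAP siRNA, and TGFβ1 with both siRNAs. Whether the control cells were transfected is not given in the labels, so the comparison with control cells holds TGFβ1 and any effect of transfection together. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

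The deposited value table held 49293 probe sets as log2 values, per the labels' columns and the range of the values, and a companion table held the same values with 202 control probe sets added. The submitters' processing notes name MAS5 without a version, and the normalization between arrays is not given in the sources used here. The deposited log2 values had not been brought to a common level, because the array medians ran from 5.97 to 6.53. The authors also deposited a comparison table with a linear ratio and a p-value for each of 4 comparisons in 49395 probe sets, per the file headers, and lists of genes past their own threshold. The test behind those deposited p-values is not stated. Converted to standard errors, the 4 p-values of a probe set implied one shared spread at 16 residual degrees of freedom, with a coefficient of variation of at most 2.33e-05 in the 1306 probe sets used, against 0.175 at 10 degrees of freedom. The 15 arrays in 5 groups give 10, so the authors' fit appears to have included arrays not analysed here.

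The value table names probe sets by identifier and the comparison table names genes without that identifier, and no table used here pairs them. Per-array tests were therefore run on unnamed probe sets, and named genes and gene lists were tested from the comparison table. The design fixed before the data were examined had asked for 1 probe set per gene, the brightest, for named genes whose 3 arrays all lie beyond those of the other group, and for list tests with an estimated correlation between genes. All of these need named values per array. Every probe set was therefore tested in the value table, the mean over a gene's probe sets was used in the comparison table, and the other conditions were left out.

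In the value table, limma 3.58.1 (lmFit and eBayes, R 4.3.3) was fitted to the log2 values as deposited over all 15 arrays, which share a single estimate of spread per probe set, with moderated tests of either direction and Benjamini-Hochberg adjustment at 0.05. The study's own threshold, over 2-fold and an unadjusted p-value under 0.05, was counted as well, with limma's p-values. In the comparison table, 45998 probe sets carried a single Entrez identifier, of which 45825 matched the RefSeq gene table of GRCh38.p14, which was used for symbols only. Another 2825 carried several identifiers and 572 carried none, and these were left out of gene values. This gave 18511 genes, 6534 with a single probe set and 11977 with several, and in 87 probe sets a symbol that a spreadsheet had turned into a date was restored through its identifier. Log2 ratios were averaged over a gene's probe sets, standard errors were derived from the deposited p-values and averaged likewise, and variances were moderated across genes with limma's squeezeVar (2.69 prior degrees of freedom). A standard error printed with a gene is therefore implied by the deposited p-values and is the same for each comparison of 2 groups. The comparisons between knockdowns, of both siRNAs with control and of the YAP by TAZ interaction were sums or differences of the 4 deposited log2 ratios.

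The 21 gene lists were part of the same design and cover TGFβ and SMAD targets, YAP/TAZ-TEAD targets, contractile and actin cytoskeleton genes, matrix proteins, collagen processing, matrix proteases, integrins and focal adhesions, Hippo components, G1/S, G2/M, p53 targets, cytokines and chemokines, interferon-stimulated genes, cholesterol synthesis, lipofibroblast genes, glycolysis and hypoxia, the unfolded protein response, and epithelial, endothelial, immune and smooth muscle markers. Each was tested with limma's cameraPR, a competitive test against all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 21 lists. Fixed correlations of 0.05 and 0.2 took the place of the estimated correlation. The listed genes not matched in the comparison table were CRIM1, P4HA2, LIMS1, WWC2, BBC3, SOD2, USP18, CYP51A1, SLC2A3, SLC16A3, SFTPA1 and MCAM. The genes named in the text were set by a rule: YAP1 and WWTR1, the gene for TAZ, throughout; for each list, up to 2 members with the largest rise and 2 with the largest fall past the threshold in each of the 4 main comparisons; the 6 largest rises and falls past the threshold in each of those, and the 4 largest in the others; and members of the contractile list. Other genes are marked where they appear as named after their values were seen.

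Alternatives were quantile normalization, centring arrays on their medians, a filter on dim probe sets (40th percentile of mean log2 value, 5.4, which left 29576), the replicate number as a block, eBayes with trend and robust settings, array weights, fits of only the groups compared, leaving out each array or each replicate number, the comparison table in place of the value table, and, for the study's threshold, a plain test on the 2 groups and a fold with an adjusted p-value. Chosen after seeing the data were the fixed correlations, list tests on ranks, quantile normalization together with the block, leaving out all 5 arrays of a replicate number, a median or a Simes p-value over a gene's probe sets, and a fit without moderation of the variance. The single probe sets of contractile genes, tested with the same moderation and adjusted over all 49395 probe sets of the comparison table, were also looked at after seeing the data. Replicate numbers come from the labels. The deviations of arrays from their group means were correlated in all 30 pairs of arrays with the same number (0.127 to 0.721, median 0.404). The 60 pairs with different numbers had a median of -0.227. Deviations sum to 0 within a group, so this negative value follows from the positive ones and is not separate evidence. All 15 arrays matched best an array of their own number. The numbers were therefore taken to pair the arrays, and the value with replicate number as a block is given beside a count from all arrays as deposited where it differed by more than 1.5 times. Named genes could not be blocked, because the comparison table holds no values per array.

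The procedures were tested on simulated data. For TGFβ1 against control in the 49293 probe sets, the fit without a block recovered 1.5% of changes of 0.5 on the log2 scale, 40.3% of changes of 1 and 97% of changes of 2, with 2 false calls among 94; with the block it recovered 7.5%, 56.7% and 95.5%, with 4 false calls among 110. In the 18511 genes of the comparison table the same sizes were recovered at 47.8%, 82.1% and 98.5%, with 8 false calls among 160, for that comparison. Over 50 simulated draws of the 21 lists, 0 lists were called on average with none shifted. With 3 lists shifted, 2.94 of these 3 were found on average. Values were drawn independently for each gene, so the draws cannot show how often correlated real genes give false list calls. The number of arrays, 3 per group, limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

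The level of one further gene, looked at after the results were seen, is not reported here.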

Results

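IMR-90 lung fibroblasts were profiled without TGFβ1, and after 72 hours of TGFβ1 at 2 ng/ml with non-targeting siRNA, TAZ siRNA, YAP siRNA or both siRNAs, with 3 arrays in each of the 5 groups. YAP and TAZ are transcriptional coactivators of the Hippo pathway, and by its title the series asks how they control the contractile program in combination. The 15 arrays measured 49293 probe sets as deposited log2 values with medians from 5.97 to 6.53, and probes for background averaged 3.48 to 3.84. Correlations between arrays of the same group ran across probe sets from 0.966 to 0.989; probe sets are not independent replicates. Named genes and gene lists come from the authors' deposited comparison table (18511 genes), in which a standard error is implied by the deposited p-values, and counts per probe set come from the deposited values per array, since the files do not pair the probe set identifiers with gene names.

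On quantile-normalized values the first principal component held 42.1% of the variance and the second 14.3%. Replicate 1 of each TGFβ1 group lay on the high side of the first component, at 51.2 with non-targeting siRNA, 79.6 with TAZ siRNA, 59.3 with YAP siRNA and 88.5 with both. The other 2 arrays with both siRNAs lay at 36.4 and 31.5, those with non-targeting siRNA at -59.1 and -43.3, and the control arrays between -53.2 and -26.0. The replicate numbers paired the arrays, and counts with the number as a block are given below beside the counts from all arrays as deposited wherever they differ by more than 1.5 times.

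**Figure D1:**
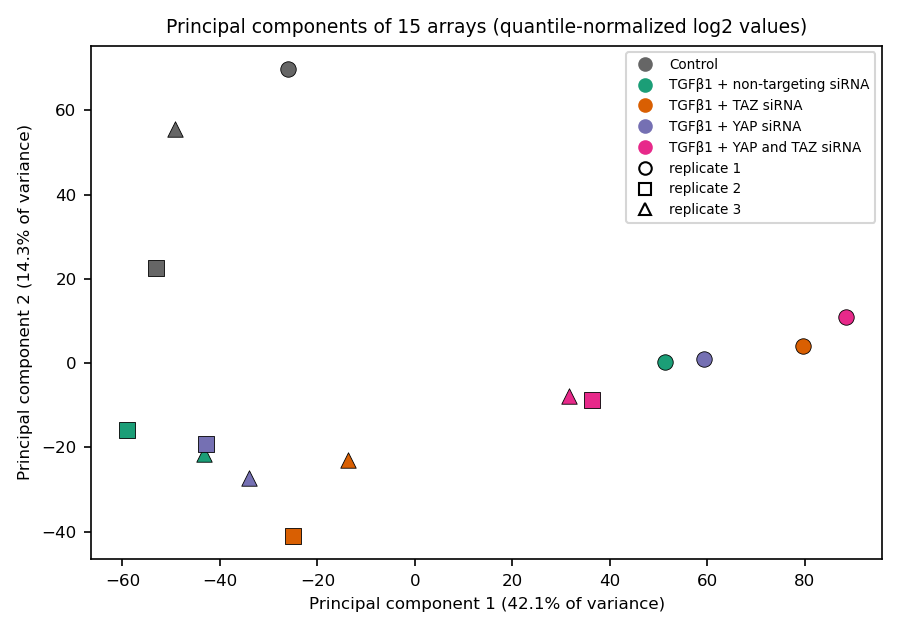
The first and second principal components of the 15 arrays after quantile normalization, with 42.1% and 14.3% of the variance on the axes; a point is 1 array, colored by group, with a marker shape for each replicate. Replicate 1 of the 4 TGFβ1 groups lies at 51.2 or above on the first component, and the other 2 arrays of the double knockdown lie at 36.4 and 31.5.

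Each siRNA lowered its own target, and the other gene's change did not pass the threshold. In the authors' deposited table, WWTR1, which encodes TAZ, fell by 1.67 on the log2 scale (implied SE 0.18, limma-adjusted p = 0.000403) with TAZ siRNA against non-targeting siRNA. With both siRNAs its change was -1.57 (adjusted p = 0.000521). YAP1 fell by 2.57 (implied SE 0.20, limma-adjusted p = 1.6e-06) with YAP siRNA, and its change with both was -2.19 (adjusted p = 2.33e-05). The change in YAP1 under TAZ siRNA was -0.18 and that in WWTR1 under YAP siRNA was -0.04, neither past the threshold. Under TGFβ1 against control, YAP1 was at -0.03 and WWTR1 at 0.05. Per array, the probe set that fell most under TAZ siRNA stood at 10.35 ± 0.32 (SD, n = 3) with non-targeting siRNA, 7.77 ± 0.39 with TAZ siRNA and 8.13 ± 0.50 with both, and at 10.28 ± 0.50 in control cells. The one that fell most under YAP siRNA stood at 11.15 ± 0.34 (SD, n = 3) with non-targeting siRNA, 8.14 ± 0.44 with YAP siRNA and 9.08 ± 0.23 with both, and at 11.39 ± 0.29 in control cells. Both probe sets are unnamed and were picked for these falls. Their falls under the single siRNAs are therefore no separate evidence for WWTR1 or YAP1.

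TGFβ1 with non-targeting siRNA against control cells, called TGFβ1 for short, holds the change under TGFβ1 together with any effect of transfection, since the labels do not say whether control cells were transfected. The authors' deposited table gave 73 genes that rose and 87 that fell (limma-adjusted p under 0.05). TGFβ and SMAD target genes rose together, with a median log2 change of 0.80 over 24 genes, 17 above 0 and 7 below, and a cameraPR-adjusted p of 4.4e-09. That call was lost at a fixed inter-gene correlation of 0.2 (adjusted p = 0.0604), which stood in for an estimated one. NOX4, an NADPH oxidase, rose by 2.08 (implied SE 0.42, adjusted p = 0.023), and PMEPA1, a feedback inhibitor of SMAD signaling, rose by 1.78 (implied SE 0.40, adjusted p = 0.0378). Matrix genes rose as a group, with a median of 0.28 over 38 genes, 31 above 0, and a cameraPR-adjusted p of 1.74e-08 (0.152 at the correlation of 0.2): COMP, a cartilage matrix protein, rose by 2.84 (implied SE 0.50) and the fibrillar collagen gene COL11A1 by 1.51 (implied SE 0.26). The lipofibroblast transcription factor genes PPARG and TCF21 fell, with changes of -1.63 (implied SE 0.21, adjusted p = 0.00155) and -2.21 (implied SE 0.40, adjusted p = 0.0112).

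Over all genes, 4 SMAD targets rose in the authors' deposited table, TGFB1 and WNT5A besides those above (named after their values were seen). When p-values were adjusted over the list alone, 13 rose. Of the matrix genes 2 rose over all genes and 5 when adjusted over the list alone. Among collagen processing genes, with a median of 0.21 and a cameraPR-adjusted p of 0.000829 (0.297 at a correlation of 0.2), the prolyl hydroxylase gene P4HA1 rose by 0.71 (implied SE 0.16), and 4 of 24 rose when adjusted over the list alone. Integrin genes changed both ways: ITGA1 rose by 1.26 and ITGB3 by 0.97, and ITGA8 and ITGB8 fell (-2.22 and -1.11). The list as a whole had an adjusted p of 0.224, and 5 members rose and 2 fell when adjusted over the list alone. The serine protease gene HTRA1 rose by 1.88 (implied SE 0.23), while PLAU, which encodes urokinase, fell by 1.03 (implied SE 0.20) and CTSB, a cathepsin, fell by 0.42 (implied SE 0.09). The protease list had an adjusted p of 0.645, with 3 rises and 4 falls when adjusted over the list alone.

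Metabolic lists and the G1/S list moved under TGFβ1 as well in the authors' deposited table, while the other cell cycle lists did not pass: G2/M genes had a median of -0.01 and a cameraPR-adjusted p of 0.683, and p53 targets a median of 0.04 and one of 0.868. Glycolysis and hypoxia genes had a median of 0.39, with 25 of 28 above 0 and a cameraPR-adjusted p of 1.1e-05 (0.152 at a correlation of 0.2, as for the next 2 lists). The phosphofructokinase gene PFKL rose by 0.49 (implied SE 0.10), and 4 rose when adjusted over the list alone. Cholesterol synthesis genes had a median of 0.27, with 21 of 23 above 0 and a cameraPR-adjusted p of 1.1e-05. IDI1, an isomerase of that pathway, rose by 0.54 (implied SE 0.11), as the 1 call over all genes and adjusted over the list alone. G1/S and DNA replication genes fell as a group, with 31 of 33 below 0, a median of -0.12 and a cameraPR-adjusted p of 2.71e-06. The helicase subunit gene MCM4 fell by 0.97 (implied SE 0.20), and 4 fell when adjusted over the list alone. The lipofibroblast list had a median of -0.05, a mean of -0.23 and a cameraPR-adjusted p of 0.00688, with 2 falls over all genes and adjusted over the list alone. The unfolded protein and amino acid stress list had a median of 0.06 and a cameraPR-adjusted p of 0.028, with ALDH18A1, a proline synthesis gene, up by 0.91 (implied SE 0.17) as the 1 call by either adjustment. These last 2 lists lost their call at a fixed inter-gene correlation of 0.05, with adjusted p-values of 0.0573 and 0.159. All 8 lists lost theirs at 0.2, with adjusted p-values from 0.0604 for SMAD targets to 0.67; an estimated correlation could not be had.

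Contractile genes, the subject of the series, did not pass the test as a list under TGFβ1, with a median of 0.15, 27 of 40 above 0 and a cameraPR-adjusted p of 0.11 in the authors' deposited table. As means over a gene's probe sets, no member passed limma's adjusted threshold over all genes or adjusted over the list alone, and 4 were higher and 2 lower at an unadjusted p under 0.05. Of the 198 single probe sets of these genes, 2 were higher and 3 lower when adjusted over all probe sets. TPM2, a tropomyosin, had 2 of its 4 at 1.34 and 1.42 (adjusted p = 0.0082 and 0.00703) and a gene mean of 0.80 (adjusted p = 0.159). VCL, which encodes vinculin, had 2 of its 4 at -0.99 and -0.71 (adjusted p = 0.0119 for each) and a gene mean of -0.47 (adjusted p = 0.13), and ACTN1, an alpha-actinin, had 1 at -0.34 (adjusted p = 0.0339). The largest gene means were 1.44 (implied SE 0.54, adjusted p = 0.334) for TAGLN, an actin-binding protein of smooth muscle, 1.05 (implied SE 0.43, adjusted p = 0.423) for TPM1, another tropomyosin, and 0.85 (implied SE 0.44, adjusted p = 0.648) for CNN1, a calponin. ACTA2, the smooth muscle actin that marks myofibroblasts, was at 0.75 (implied SE 0.33, adjusted p = 0.488), and its 3 probe sets gave 1.80, 0.17 and 0.27.

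The largest rises past the threshold under TGFβ1 in the authors' deposited table, besides COMP, were those of RASGRP3, a guanine nucleotide exchange factor, by 3.18 (implied SE 0.65), and TYRP1, a melanosome enzyme, by 2.92 (implied SE 0.37). The globin gene HBD rose by 2.56 (implied SE 0.58), the cadherin gene CDH6 by 2.53 (implied SE 0.53) and IGFBP3, an IGF-binding protein, by 2.48 (implied SE 0.56). The largest falls, besides those of ITGA8 and TCF21, were in GUCY1B1, a subunit of soluble guanylate cyclase (-2.67, implied SE 0.58), and CCBE1 (-2.45, implied SE 0.45). The serotonin receptor gene HTR2B (-2.42, implied SE 0.39) and the scavenger receptor gene COLEC12 (-2.31, implied SE 0.52) followed. IGFBP3 was the 1 called member of the YAP/TAZ-TEAD target list over all genes and adjusted over the list alone, and that list had an adjusted p of 0.683. Among probe sets, 49 rose and 94 fell (limma), or 367 and 919 with the replicate block. By limma's p-values, 793 passed the study's own threshold of over 2-fold and an unadjusted p under 0.05. By the authors' deposited ratios and p-values, without moderation, 548 passed it. Against non-targeting siRNA, those deposited values gave 29, 12 and 660 under TAZ siRNA, YAP siRNA and both. After quantile normalization, which removed a shift of -0.14 in the median log2 change, 103 rose and 60 fell, so the balance of rises and falls depended on scaling; the median change in the comparison table was 0.002. In fits without the block, the count of 143 changed when single arrays were left out. It was 21, 408 and 23 without control replicate 1, 2 or 3, and 25 and 56 without non-targeting replicate 1 or 3. Leaving out 1 array also puts the shift of its replicate number into the group difference, here and in the later counts without single arrays. None of the 143 changed direction, and all 143 were also called with the block. The 793 became 1237 without control replicate 2.

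TAZ siRNA in TGFβ1-treated cells changed few single genes and shifted several lists. WWTR1 was the 1 gene past the limma threshold in the authors' deposited table. At an unadjusted p under 0.05 there were 523 genes, against 926 expected by chance. These p-values could not be blocked by replicate number and may run conservative. A count below 926, here or further below, therefore does not show that genes were unchanged. Contractile genes fell as a list, with 37 of 40 below 0, a median of -0.23 and a cameraPR-adjusted p of 3.5e-11, a call lost at a correlation of 0.2 (adjusted p = 0.104). TAGLN was at -0.87 (implied SE 0.54) and CNN1 at -0.87 (implied SE 0.44). MYLK, which encodes myosin light chain kinase, was at -0.86 (implied SE 0.43) and the smooth muscle actin ACTG2 at -0.78 (implied SE 0.41), none past the threshold. Cytokine and chemokine genes rose as a list, with 23 of 27 above 0, a median of 0.62 and a cameraPR-adjusted p of 7.46e-05 (0.185 at a correlation of 0.2).

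YAP/TAZ-TEAD target genes fell as a list under TAZ siRNA in the authors' deposited table (median -0.21, cameraPR-adjusted p = 0.000239), as did G2/M and mitosis genes (median -0.11, cameraPR-adjusted p = 1.55e-08) and cholesterol synthesis genes (median -0.17, 22 of 23 below 0, cameraPR-adjusted p = 2.55e-05). The list of p53 targets and cell-cycle inhibitors rose (median 0.16, cameraPR-adjusted p = 2.55e-05). At a correlation of 0.2 these 4 lists lost the call, with adjusted p-values from 0.111 to 0.185. No list member passed limma's threshold over all genes. Adjusted over the list alone, the death receptor gene FAS was higher and RBMS3, a TEAD target, and FERMT2, a kindlin of focal adhesions, were lower (all 3 named after their values were seen). At an unadjusted p under 0.05, 6 contractile genes were lower and 0 higher, and 2 cytokine genes higher and 0 lower. Another 6 lists fell at the preset correlation and lost the call at 0.05: G1/S (adjusted p = 0.067 there), integrins and focal adhesions (0.0714), collagen processing (0.108), smooth muscle markers (0.108), matrix proteins (0.158) and Hippo components (0.158). At 0.2 no list passed under TAZ siRNA.

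Among probe sets, 2 fell and 0 rose with TAZ siRNA (limma, 1939 at an unadjusted p under 0.05, or 3854 with the replicate block), and the same 2 passed with the replicate block. Without non-targeting replicate 1 or 3, or TAZ siRNA replicate 1 or 2, the count was 0. The study's own threshold was passed by 95 probe sets, or 199 with the block. That count of 95 became 554 without non-targeting replicate 1, and 225 and 251 without TAZ siRNA replicate 2 or 3.

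YAP siRNA in TGFβ1-treated cells changed 2 named genes past the threshold in the authors' deposited table. YAP1 fell, as given above, and SMIM14, a small membrane protein, fell by 1.52 (implied SE 0.20, limma-adjusted p = 0.00328). In all, 313 genes had an unadjusted p under 0.05 against 926 expected. Cytokine and chemokine genes rose as a list, with a median of 0.34, 25 of 27 above 0 and a cameraPR-adjusted p of 0.000485, and p53 targets rose, with a median of 0.15, 21 of 24 above 0 and a cameraPR-adjusted p of 5.13e-05. Contractile genes fell as a list (median -0.10, 36 of 40 below 0) and so did G2/M genes (median -0.07, 26 of 33 below 0), both with a cameraPR-adjusted p of 0.00155. These 4 lists lost the call at a correlation of 0.2, with adjusted p-values from 0.569 to 0.756. The comparisons of TAZ siRNA, YAP siRNA and both siRNAs all use the same non-targeting arrays. A list shift that repeats among them is therefore not independent support.

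The contractile and G2/M calls under YAP siRNA were lost at a fixed correlation of 0.05, with an adjusted p of 0.0612 for each in the authors' deposited table. TAGLN stood at -0.47 (implied SE 0.54), MYL9, a myosin regulatory light chain, at -0.47 (implied SE 0.35), MYLK at -0.38 (implied SE 0.43) and CNN1 at -0.35 (implied SE 0.44), none past the threshold. Over all genes, 0 list members passed limma's threshold; adjusted over the list alone, FERMT2, named after its value was seen, was lower at -0.52, and 0 members of the contractile list had an unadjusted p under 0.05. The YAP/TAZ-TEAD target list had a median of -0.04 and an adjusted p of 0.823. Of probe sets, 10 fell and 0 rose (limma, 2454 at an unadjusted p under 0.05, or 4324 with the replicate block), the same 10 with the block, and 36 passed the study's threshold. The median log2 change was -0.138 as deposited, and after quantile normalization 1540 had an unadjusted p under 0.05, or 2683 with the block. The 10 became 5 without the 5 arrays of replicate 2 and 0 without those of replicate 3. The 36 became 160 and 148 without non-targeting replicate 1 or 2, and 97, 63 and 68 without YAP siRNA replicate 1, 2 or 3.

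Both siRNAs together in TGFβ1-treated cells, against non-targeting siRNA, addressed the question in the title: contractile genes fell and cytokine genes rose. The contractile list had, in the authors' deposited table, a median of -0.40 and a mean of -0.67, with 38 of 40 genes below 0 and a cameraPR-adjusted p of 1.41e-17. TAGLN fell by 3.00 (implied SE 0.54, adjusted p = 0.0162) and MYLK fell by 2.31 (implied SE 0.43, adjusted p = 0.0179). CNN1 fell by 2.24 (implied SE 0.44, adjusted p = 0.0228) and ACTG2 fell by 2.06 (implied SE 0.41, adjusted p = 0.0263). The 5 probe sets of ACTG2 gave -3.37, -3.34, -3.17, -0.27 and -0.15, and the 6 of TAGLN ran from -3.12 to -2.82. Gene means therefore do not rank the sizes of these falls. Between these groups the 3′ minus 5′ difference of the beta-actin control probes, read as a sign of RNA quality, went from 0.238 ± 0.082 (SD, n = 3) to 0.518 ± 0.136, and that of GAPDH from -0.111 ± 0.055 to -0.114 ± 0.026. Cytokine and chemokine genes rose, with a median of 1.28 over 27 genes, 23 above 0 and a cameraPR-adjusted p of 1.73e-14. IL1B, which encodes interleukin-1β, rose by 3.08 (implied SE 0.63, adjusted p = 0.0273) and IL24, a cytokine of the IL-10 family, by 2.07 (implied SE 0.26, adjusted p = 0.001). Across all genes, 51 rose and 43 fell (limma-adjusted p under 0.05).

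Of the 40 contractile genes, 7 fell over all genes tested and 17 when adjusted over the list alone in the authors' deposited table. Besides the 4 above, MYL9 fell by 1.67 (implied SE 0.35), LMOD1, a leiomodin that nucleates actin filaments, fell by 1.11 (implied SE 0.24), and FLNA, which encodes the actin cross-linker filamin A, fell by 0.89 (implied SE 0.16). The 5 probe sets of LMOD1 ran from -2.34 to -0.22. TPM1 was at -1.66 (implied SE 0.43, adjusted p = 0.0957) and ACTA2 at -0.85 (implied SE 0.33, adjusted p = 0.301), with values of -2.13, -0.22 and -0.21 in its 3 probe sets. Of the 198 single probe sets of the list, 36 were lower and 0 higher when adjusted over all probe sets, in 11 genes: the 7 above, TPM1, ACTA2 (1 of 3, the one at -2.13, adjusted p = 0.0377), TPM4 and ACTN1. The members above 0 were SVIL at 0.15 and ROCK1 at 0.29. The contractile and cytokine lists kept adjusted p-values of 0.00429 at a fixed correlation of 0.2, the strictest tried. Smooth muscle and pericyte markers fell as a list (median -0.20, cameraPR-adjusted p = 0.00177, 0.227 at a correlation of 0.2), with CNN1, LMOD1 and ACTG2, which the contractile list also holds, as its 3 called members over all genes and adjusted over the list alone.

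**Figure D2:**
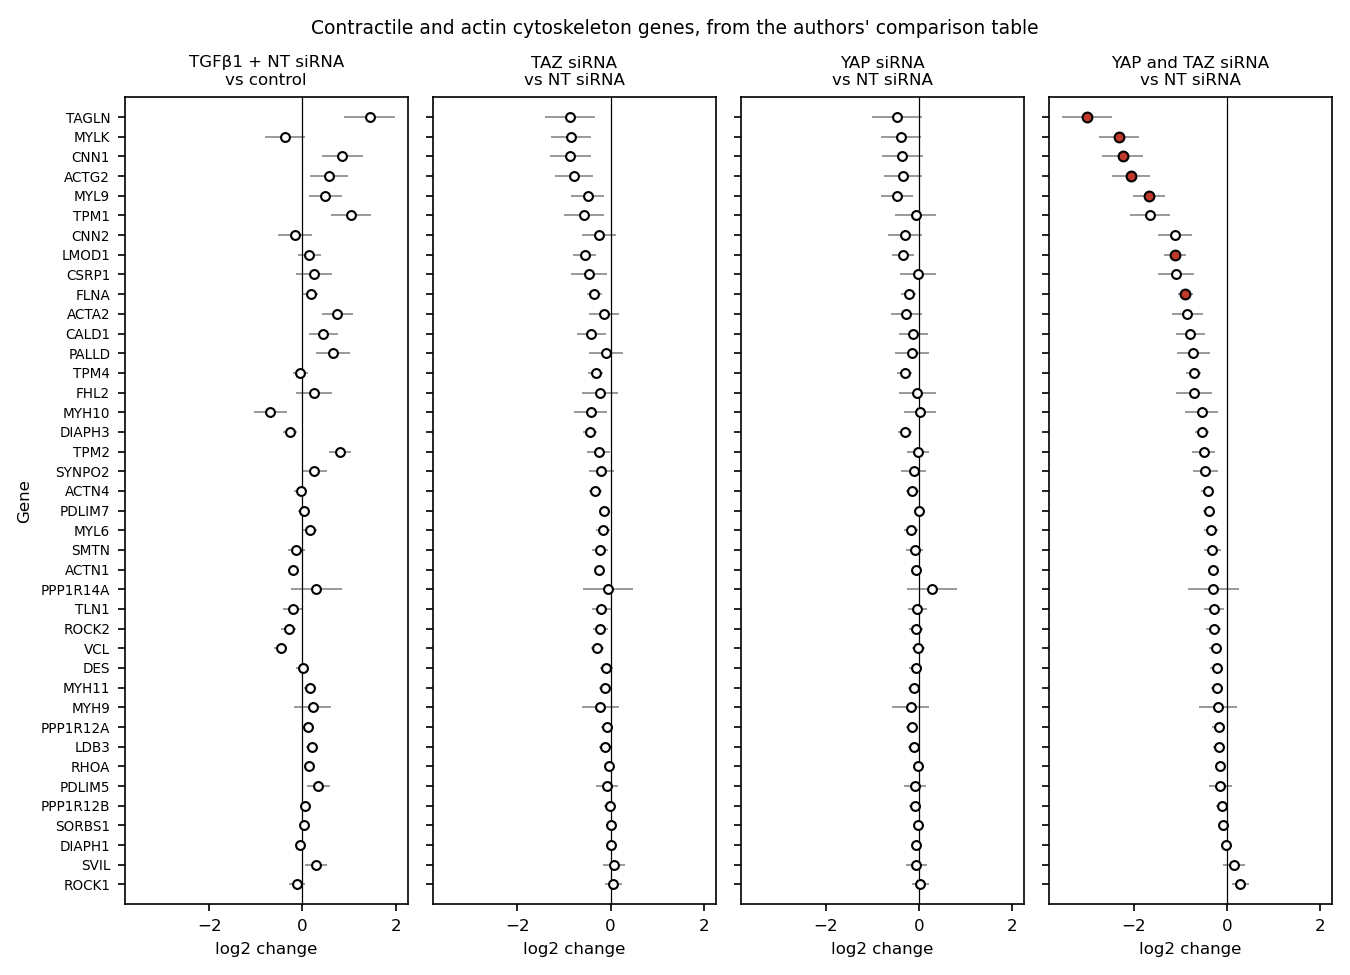
Log2 changes of the contractile genes against non-targeting siRNA, or against control for TGFβ1, from the authors' deposited table, with bars of 1 implied standard error and filled points for genes past the limma-adjusted threshold. TAGLN lies at 1.44 under TGFβ1 against control and at -3.00 under both siRNAs against non-targeting siRNA.

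Of the cytokine genes, 2 rose over all genes tested and 14 when adjusted over the list alone under both siRNAs in the authors' deposited table. The other 12, named after their values were seen, included the chemokine genes CCL20 at 3.92 and CXCL8 at 3.39 and the cytokine gene IL1A at 3.27. YAP/TAZ-TEAD target genes fell as a list, with a median of -0.20, a mean of -0.58 and a cameraPR-adjusted p of 0.00239 (0.0267 at a correlation of 0.05 and 0.28 at 0.2). No target passed limma's threshold over all genes, with 2 higher and 8 lower at an unadjusted p under 0.05, and 6 were lower and 1 higher when adjusted over the list alone. The matricellular genes CCN1 at -3.55 (implied SE 0.86, adjusted p = 0.0728) and CCN2 at -2.14 (implied SE 0.64, adjusted p = 0.164), named after their values were seen, had the largest changes.

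The G2/M, p53, adhesion and matrix lists moved as well under both siRNAs in the authors' deposited table, and the G1/S list did not pass (median -0.07, cameraPR-adjusted p = 0.0617). G2/M genes fell as a list (median -0.20, 30 of 33 below 0, cameraPR-adjusted p = 1.02e-08, 0.0738 at a correlation of 0.2), with 0 calls over all genes (limma), 1 lower adjusted over the list alone and 14 lower at an unadjusted p under 0.05. The p53 list rose (median 0.23, cameraPR-adjusted p = 9.18e-06, 0.131 at 0.2), and GDF15, a stress-induced cytokine, rose by 1.44 (implied SE 0.29), with 7 genes higher and 1 lower when adjusted over the list alone. Integrin and focal adhesion genes fell (median -0.14, cameraPR-adjusted p = 0.00902, 0.0662 at a correlation of 0.05). FERMT2 fell by 1.15 (implied SE 0.14) and TGFB1I1, which encodes the adhesion adaptor Hic-5, fell by 0.79 (implied SE 0.12), and 4 fell when adjusted over the list alone. Matrix genes fell (median -0.23, cameraPR-adjusted p = 0.00425, 0.0655 at 0.05), with FBLN5, an elastic fiber protein, at -1.41 (implied SE 0.26) and 1 gene higher and 1 lower when adjusted over the list alone.

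The remaining lists past the threshold under both siRNAs in the authors' deposited table had few single genes behind them. Cholesterol synthesis genes fell (median -0.23, cameraPR-adjusted p = 0.000442, 0.228 at a correlation of 0.2) and glycolysis and hypoxia genes rose (median 0.40, 23 of 28 above 0, cameraPR-adjusted p = 0.00103, 0.28 at 0.2), both with 0 limma calls over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 5 cholesterol genes were lower and 0 higher, and 3 glycolysis genes higher and 1 lower. SMAD targets rose (median 0.24, cameraPR-adjusted p = 0.00902, 0.0655 at 0.05) with 0 limma calls over all genes, 2 higher adjusted over the list alone, and 4 higher and 1 lower unadjusted. Matrix proteases rose (median 0.17, cameraPR-adjusted p = 0.00902, 0.0655 at 0.05) with CTSB up by 0.44 (implied SE 0.09) as the 1 call by either adjustment. Interferon-stimulated genes (median -0.13, cameraPR-adjusted p = 0.0406) and collagen processing genes (median -0.19, cameraPR-adjusted p = 0.0482) fell, each with an adjusted p of 0.166 at 0.05. At a correlation of 0.2, 12 of the 14 lists lost their call.

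The largest rises past the threshold under both siRNAs in the authors' deposited table, after IL1B, were those of CHST2, a sulfotransferase, by 2.37 (implied SE 0.44), IL24, and CNIH3 by 2.04 (implied SE 0.39). GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 1.72 (implied SE 0.33) and DUSP4, a MAP kinase phosphatase, by 1.67 (implied SE 0.29). The largest falls, besides TAGLN, MYLK and CNN1, were in the globin genes HBG1 (-3.27, implied SE 0.59) and HBD (-2.93, implied SE 0.58) and in WFDC1 (-2.51, implied SE 0.39). Epithelial, endothelial and immune markers had medians between -0.03 and -0.01 and cameraPR-adjusted p-values of 0.837, 0.913 and 0.747. Among probe sets, 25 rose and 65 fell (limma), or 1413 and 906 with the replicate block, and after quantile normalization 44 rose and 55 fell; 1042 passed the study's threshold. The first component placed replicate 1 of every TGFβ1 group near the double knockdown, and without the 5 arrays of replicate 1 the count was 1689, against 0 without replicate 2 or without replicate 3. Leaving out single arrays gave 185, 18 and 6 without non-targeting replicate 1, 2 or 3, and 40, 18 and 10 without double knockdown replicate 1, 2 or 3. For the 1042 past the study's threshold, the values were 2440 and 635 without non-targeting replicate 1 or 2, and 2137, 623 and 539 without the arrays of replicate 1, 2 or 3.

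**Figure D3:**
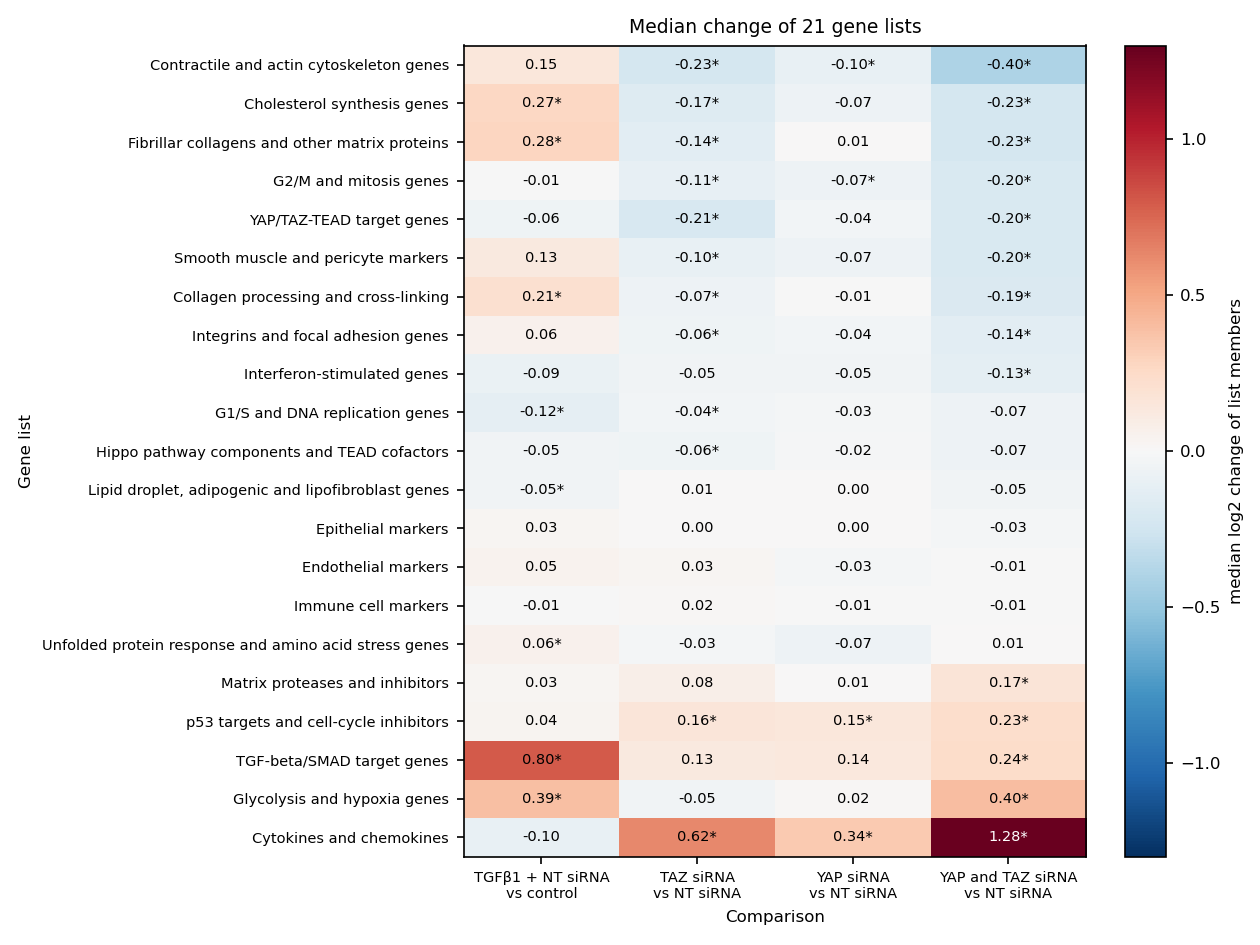
Median log2 change of each gene list in the 4 main comparisons, from the authors' deposited table, as a color scale with the value in each cell and an asterisk for lists past the cameraPR-adjusted threshold. The contractile list runs from 0.15 under TGFβ1 to -0.40 under both siRNAs, and the cytokine list from -0.10 to 1.28.

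The knockdowns were also compared with each other, to ask whether both siRNAs did more than a single one. Against TAZ siRNA alone, both siRNAs gave lower contractile genes (median -0.16, 36 of 40 below 0, cameraPR-adjusted p = 4.99e-08, 0.149 at a correlation of 0.2) and higher cytokine genes (median 0.71, cameraPR-adjusted p = 4.5e-11) in the authors' deposited table. Against YAP siRNA alone, contractile genes were lower (median -0.30, 37 of 40 below 0, cameraPR-adjusted p = 1.19e-14), cytokine genes higher (median 0.90, cameraPR-adjusted p = 1.72e-10) and YAP/TAZ-TEAD targets lower (median -0.22, cameraPR-adjusted p = 0.000103, 0.155 at a correlation of 0.2). Of single genes, YAP1 fell by 2.01 (implied SE 0.20) against TAZ siRNA as the 1 call there. Against YAP siRNA, WWTR1 fell by 1.53 (implied SE 0.18) and EFEMP1, a fibulin, fell by 1.51 (implied SE 0.21). IL24 rose there by 1.75 (implied SE 0.26), RESF1 by 1.36 (implied SE 0.23), the adhesion receptor gene CXADR by 1.08 (implied SE 0.17) and VPS54 by 0.39 (implied SE 0.07).

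Adjusted over the list alone, 6 contractile genes were lower against TAZ siRNA and 11 against YAP siRNA in the authors' deposited table, with 0 limma calls over all genes and 12 and 14 genes lower at an unadjusted p under 0.05. Against TAZ siRNA 7 lists passed, and 3 held at a correlation of 0.05 (contractile, cytokine and glycolysis genes), and at 0.2 the cytokine list held (adjusted p = 0.032) and the contractile list did not (0.149). The median log2 change of probe sets was 0.106 there. Against YAP siRNA 12 lists passed, 8 held at 0.05, and the contractile and cytokine lists held at 0.2, both with an adjusted p of 0.0249. By limma, 5 probe sets (all lower) changed against TAZ siRNA and 2 against YAP siRNA (1 in each direction). With the replicate block these counts were 33 and 1906, the latter with 1647 higher and 259 lower. Against YAP siRNA, quantile normalization with the block gave 645, with 266 higher and 379 lower, so the balance depended on scaling. The median log2 shift that this normalization removed was 0.18. Without the arrays of replicate 1 the counts were 210 and 1466. The count of 5 was 0 without TAZ siRNA replicate 1 or 3 or double knockdown replicate 2 or 3, and 2 without double knockdown replicate 1; the count of 2 was 0 without any single YAP siRNA array or double knockdown replicate 2.

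YAP siRNA against TAZ siRNA compared the 2 single knockdowns. Contractile genes of the authors' deposited table were higher with YAP siRNA than with TAZ siRNA (median 0.14, 29 of 40 above 0, cameraPR-adjusted p = 0.000351), and so were YAP/TAZ-TEAD targets (median 0.10, cameraPR-adjusted p = 0.00012), cholesterol synthesis genes (median 0.14, cameraPR-adjusted p = 0.00012) and matrix genes (median 0.13, cameraPR-adjusted p = 0.000675). These 4 lists held at a correlation of 0.05 and none held at 0.2, where the contractile list had an adjusted p of 0.639. Collagen processing and G2/M genes, each with a cameraPR-adjusted p of 0.0094, did not hold at 0.05, with adjusted p-values of 0.0972 and 0.105. Besides YAP1 at -2.40 and WWTR1 at 1.63, SMIM14 was lower with YAP siRNA at -1.27 (implied SE 0.20) and TRIM37, a ubiquitin ligase, higher at 0.71 (implied SE 0.12), and these were the 4 genes past limma's threshold. Among probe sets, 3 were higher and 10 lower, and the total of 13 was between 6 and 8 without any single array of the 2 groups.

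Both siRNAs with TGFβ1 against control cells showed where the double knockdown left the cells. In the authors' deposited table SMAD targets stayed above control (median 1.05, 11 higher and 1 lower, cameraPR-adjusted p = 4.53e-10), glycolysis genes were higher (median 0.78, cameraPR-adjusted p = 7.67e-09, 0.0633 at a correlation of 0.2) and cytokine genes were higher (median 1.29, cameraPR-adjusted p = 6.01e-07, 0.117 at 0.2). Contractile genes were below control (median -0.40, cameraPR-adjusted p = 2.38e-07, 0.121 at 0.2), with 10 lower over all genes and 17 adjusted over the list alone. The beta-actin 3′ minus 5′ difference was 0.518 ± 0.136 (SD, n = 3) with both siRNAs and 0.244 ± 0.015 in control. It was 0.276 ± 0.040 with YAP siRNA alone and 0.296 ± 0.148 with TAZ siRNA alone. That of GAPDH was -0.114 ± 0.026 with both and -0.155 ± 0.056 in control. RASGRP3 was higher by 4.59 (implied SE 0.65), CBLN2 by 4.82 (implied SE 0.95), CCL20 by 5.11 (implied SE 1.47) and CXCL8 by 4.63 (implied SE 1.25). Lowest of all, FGL2 was at -4.60 (implied SE 0.89), CCN1 at -3.90 (implied SE 0.86), IFIT1, an interferon-stimulated gene, at -3.85 (implied SE 0.81) and ADH1B at -3.66 (implied SE 0.73). YAP1 and WWTR1 were at -2.22 and -1.52.

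Adjusted over the list alone, 14 SMAD targets were higher and 3 lower than control, 10 glycolysis genes higher and 1 lower, and 10 cytokine genes higher and 2 lower in the authors' deposited table. Across all genes, 487 were higher and 604 lower (limma). Of the 10 lists past the threshold, 8 held at a correlation of 0.05, and proteases (adjusted p = 0.0917) and lipofibroblast genes (0.145) did not; at 0.2 only SMAD targets held, with an adjusted p of 0.0354. By limma, 433 probe sets were higher and 1296 lower, or 2407 and 4285 with the replicate block, and quantile normalization gave 977 and 1044. The total of 1729 was 416 and 468 without control replicate 1 or 3, and 489, 798 and 663 without double knockdown replicate 1, 2 or 3.

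The interaction of YAP and TAZ asked whether the double knockdown differed from the sum of the single ones. No gene passed the limma threshold in the authors' deposited table (243 at an unadjusted p under 0.05, against 926 expected) and no probe set in the values per array (2520 unadjusted, or 6427 with the replicate block, which also called 0). The median interaction of probe sets was 0.253 as deposited, and after quantile normalization 1364 were unadjusted calls, or 2648 with the block, and 0 adjusted in both. YAP1 had an interaction of 0.56 (implied SE 0.28) and WWTR1 of 0.14 (implied SE 0.26). As a list, glycolysis and hypoxia genes had a positive interaction, with a median of 0.34, 28 of 28 genes above 0 and a cameraPR-adjusted p of 1.49e-06 (0.00155 at a correlation of 0.05, 0.342 at 0.2). Cytokine genes had a median of 0.35 (cameraPR-adjusted p = 0.00275), and matrix and contractile genes medians of -0.15 and -0.10 (cameraPR-adjusted p = 0.0245 and 0.0288); these 3 lost the call at a correlation of 0.05, with adjusted p-values of 0.0722, 0.297 and 0.297 (0.969 for each at 0.2).

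Whether knockdown undid the TGFβ1 response was asked gene by gene. Of the 73 genes that TGFβ1 raised in the authors' deposited table, 3 were lowered by both siRNAs (ALKAL1, HBD and TFG) and 0 by either single siRNA, by limma. Of the 87 it lowered, 3 were raised by both (CFTR, CMTM7 and CTSB) and 0 by a single siRNA. ALKAL1, TFG, CFTR and CMTM7 were named after their values were seen. Independent lists of these sizes would share 0.17 genes raised and then lowered by both, and 0.24 lowered and then raised. The 2 comparisons share the non-targeting arrays, which favours opposite directions, so their lists are not independent. A simulation of unchanged groups sharing those arrays gave 0 genes raised and then lowered. It held no changed genes, so neither value can decide on chance. The 73 raised genes had a median of -0.15 under both siRNAs, with 44 below 0, and the 87 lowered ones a median of 0.03, with 46 above 0. In the values per array 2 raised probe sets were lowered by both siRNAs, or 75 with the replicate block. The count of 2 was 0 without control replicate 1 or 3 or non-targeting replicate 1 or 3, 4 and 6 without control or non-targeting replicate 2, 1 without any single double knockdown array and 11 without the arrays of replicate 1.

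The authors' own deposited gene lists, 299 genes for TGFβ1 and 363 for both siRNAs, shared 49 genes, of which 31 rose with TGFβ1 and fell with both siRNAs, 5 fell and then rose, 6 rose in both and 7 fell in both. Those lists were chosen on these samples and are not independent evidence of a direction. The authors' comparison table also marks 810 genes for contraction, without giving the source of the mark. Under TGFβ1, 12 of these rose and 10 fell (17 and 12 adjusted over the list alone), which is 2.72% against 0.78% of other genes (Fisher's exact test of either direction, p = 1.9e-06, adjusted p = 1.71e-05 over the 9 comparisons). Under both siRNAs, 2 rose and 7 fell (7 and 16 adjusted over the list alone), 1.11% against 0.48% (Fisher's exact test, p = 0.0218), which did not pass when adjusted over the 9 comparisons (adjusted p = 0.0654). Both siRNAs against control gave 8.27% against 5.78% (adjusted p = 0.0211). Fisher's test treats genes as independent, and the marked genes were not matched to the others by signal level or number of probe sets. Its p-values may therefore be too small. As a list the marked genes did not shift one way past the threshold, with cameraPR p-values of 0.627 under TGFβ1, 0.894 under both siRNAs and 0.808 for both against control, unadjusted.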

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

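The fixed correlations of 0.05 and 0.2, the placing of replicate 1 in the draws, and the tests of shared state, scaling and RNA degradation for replicate 1, were chosen after the results were seen; the comparisons between knockdowns and the interaction were planned.

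The 2 single knockdowns differed from each other, by a direct limma test in the authors' deposited table, in YAP1 (-2.40, YAP siRNA minus TAZ siRNA), SMIM14 (-1.27), TRIM37 (0.71) and WWTR1 (1.63). YAP1 and WWTR1 are the targets themselves. Of the other 2 genes, SMIM14 was also below non-targeting siRNA with YAP siRNA, at -1.52. Against non-targeting siRNA, the 4 probe sets of TRIM37 lay at -0.60 to -0.52 with TAZ siRNA and at 0.12 to 0.19 with YAP siRNA. As a gene, by the mean over its probe sets, TRIM37 passed the threshold in neither. With both siRNAs the probe sets of TRIM37 lay at -0.37 to -0.16 and those of SMIM14 at -1.46 and -1.43.

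The effect of YAP siRNA differed with and without TAZ siRNA, by the interaction test, in 4 gene lists. Glycolysis and hypoxia genes had a median interaction of 0.34 and all 28 members above 0, cytokine genes a median of 0.35, matrix genes -0.15 and contractile genes -0.10. At a fixed correlation of 0.05 the glycolysis list held, with an adjusted p of 0.00155, and the other 3 did not (0.0722, 0.297 and 0.297). At 0.2 none of the 4 held (0.342 for the glycolysis list). For single genes the count was 0 in the real groups and up to 7229 in 99 other draws of the 12 arrays. No draw can give fewer than 0 (100 of 100 gave as many), so the draws say nothing about chance for that count. Draws that call so many probe sets may reflect a structure of the samples other than the groups, or the groups' own differences, which were not told apart. In the 3 draws with any call, 3 or 4 of the 4 replicate 1 arrays entered the interaction with the same sign. Of the 6 draws with all 4 so placed, 1 made calls (7229), and the 47 draws with 2 of each sign made 0.

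Arrays of replicate 1 stood apart in all 4 TGFβ1 groups. Scaling of the arrays was argued against, because they stood apart on quantile-normalized values too: on the first component the smallest gap to the nearest other array of the group was 52.04, against at most 15.72 between replicates 2 and 3. RNA degradation stays open: the GAPDH 3′ minus 5′ difference was 0.051 higher in replicate 1 (-0.092 ± 0.029, SD, n = 4) than in the other replicates (-0.143 ± 0.043, SD, n = 8), and that of beta-actin was 0.121 higher (0.412 ± 0.119 against 0.292 ± 0.151). The first is small, and the second goes the way of degradation but is smaller than the SD of the other replicates. That SD also holds differences between groups. Within groups, the beta-actin difference of replicate 1 was the highest with non-targeting siRNA (0.308), TAZ siRNA (0.465) and YAP siRNA (0.320). With both siRNAs it lay between the other arrays (0.556, against 0.367 and 0.630). Another candidate explanation is a state of those cells shared with the double knockdown. In the single knockdowns, the deviation of replicate 1 correlated at 0.581 or more across probe sets with the change under both siRNAs in replicates 2 and 3. The same deviation in control cells gave 0.236, and genes are not independent replicates. Arrays of replicates 2 and 3 enter both terms, and arrays of a number share deviations, so part of this correlation may be built in. Nothing in the labels tells what that state was, and a difference in culture, density or handling on the day was not tested.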

How the results depend on the processing

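The combination of quantile normalization with the replicate block, leaving out a whole replicate number, the Simes p-value, the median over probe sets, the fit without moderation, ranks and the fixed correlations were chosen after the results were seen; the other alternatives were planned. The 79 values of named genes include those of YAP1 and WWTR1 in every comparison, whether past the threshold or not. With the median over probe sets all kept their direction, 78 stayed on the same side of the threshold and 1 lost its call. A fit without moderation leaves the log2 changes as they are, so it cannot test direction. There, 51 stayed on the same side of the threshold and 28 lost their call. Counts were less stable, and their causes were not tested unless stated. Few arrays limit precision, and dim probe sets lie near the background level of 3.48 to 3.84.

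With the replicate block, which removes a shift shared by arrays of a number and lowers the median residual SD from 0.272 to 0.224, 1286 probe sets changed under TGFβ1, 2319 under both siRNAs, 33 for both siRNAs against TAZ siRNA, 1906 against YAP siRNA and 6692 against control, 199 passed the study's threshold under TAZ siRNA, and 75 raised probe sets were lowered by both siRNAs. All calls made without the block were also made with it. With quantile normalization and the block these were 1255, 2803, 44, 645, 7677, 183 and 126, and 28 for YAP siRNA against TAZ siRNA. Quantile normalization alone gave 8 for both siRNAs against TAZ siRNA, 11 against YAP siRNA and 5 raised probe sets lowered by both; centring on medians gave 8, 17 and 5; the other 13 counts under each stayed within 1.5 times. Of the probe sets called, 65.7% were lower under TGFβ1 as deposited and 36.8% after quantile normalization, and 72.2% and 55.6% under both siRNAs. The filter on dim probe sets moved 1 of 16 counts, the study's threshold under YAP siRNA, to 22. Trend and robust settings gave 13 for both siRNAs against YAP siRNA and 4 raised probe sets lowered by both.

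Array weights, which gave control replicate 3 a weight of 4.91 and non-targeting replicate 3 a weight of 2.56, raised the counts to 3992 under TGFβ1, 1718 under both siRNAs, 8 against TAZ siRNA, 4210 against YAP siRNA and 10432 against control. The study's threshold was then passed by 1224, 260, 155 and 1742 probe sets under TGFβ1, TAZ siRNA, YAP siRNA and both, and 2 raised probe sets were lowered by YAP siRNA and 173 by both. Fits of only the groups compared, with fewer arrays for the spread, gave 2 under TGFβ1, 0 under TAZ siRNA, 4 under YAP siRNA, 0 under both, 0 for both against TAZ siRNA, 0 against YAP siRNA, 0 for YAP siRNA against TAZ siRNA, 3541 for both against control and 0 raised probe sets lowered by both. For the study's threshold, the plain test on the 2 groups gave 467, 33 and 544 under TGFβ1, TAZ siRNA and both, and a fold with an adjusted p-value gave 133, 2, 10 and 82 under TGFβ1, TAZ siRNA, YAP siRNA and both.

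The authors' comparison table in place of the values per array gave, per probe set, 871 under TGFβ1, 7 under TAZ siRNA, 17 under YAP siRNA, 659 under both, 15 for both against TAZ siRNA, 49 against YAP siRNA, 30 for YAP siRNA against TAZ siRNA, 4497 for both against control, 38 and 12 past the study's threshold under TAZ siRNA and YAP siRNA, and 23 raised probe sets lowered by both. Per gene it gave 1, 2, 1, 6, 4 and 1091 under TAZ siRNA, under YAP siRNA, for both against TAZ siRNA, for both against YAP siRNA, for YAP siRNA against TAZ siRNA and for both against control, and 163, 13, 3 and 230 past the study's threshold; genes and probe sets are different units. Within that table, the Simes p-value gave 360 genes under TGFβ1, 2 under TAZ siRNA, 296 under both, 17 for both against YAP siRNA, 9 for YAP siRNA against TAZ siRNA and 1885 for both against control. Without moderation, 82 genes passed under TGFβ1, 3 for both against YAP siRNA and 2 for YAP siRNA against TAZ siRNA. A correlation of 0.05 left 6 lists under TAZ siRNA, 2 under YAP siRNA and 8 under both, and 0.2 left 0 under TGFβ1, 0 under TAZ siRNA, 0 under YAP siRNA and 2 under both; ranks left every count of lists within 1.5 times.

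Leaving out single arrays or a whole replicate number gave 1 (without replicate 3) to 408 (without control replicate 2) probe sets under TGFβ1, 0 to 2 under TAZ siRNA, 0 (without replicate 3) to 11 under YAP siRNA, 0 (without replicate 2 or 3) to 1689 (without replicate 1) under both, 0 to 210 (without replicate 1) for both against TAZ siRNA, 0 to 1466 (without replicate 1) against YAP siRNA, 0 (without replicate 3) to 8 for YAP siRNA against TAZ siRNA, 1 (without replicate 3) to 1888 for both against control and 0 to 0 for the interaction. The study's threshold was passed by 659 to 1237 under TGFβ1, 76 to 554 under TAZ siRNA, 49 to 160 under YAP siRNA and 539 to 2440 under both. Raised probe sets lowered by TAZ siRNA and by YAP siRNA stayed at 0 to 0, and those lowered by both ran from 0 to 11 (without replicate 1). With 2 arrays left in a group, the fit pools the spread over all groups. None of these fits held the replicate block, so leaving out a single array also put the shift of its replicate number into the group difference. Not run were a pseudocount, since the values are already log2, an estimated correlation and the brightest probe set of a gene, which need named values per array, and values per array from the workbook, whose sheet holds comparisons; all probe sets tested as separate features is the reported fit.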

Other observations

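The tests of RNA degradation and of the ACTB probe sets, the draws within replicate numbers, and the genes FN1, COL1A1, ACTB and ACTG1, were chosen after the results were seen; the test of scaling for the actin controls, that of a general reversal and the other splits of the arrays were planned.

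The matrix genes FN1 and COL1A1 did not pass the threshold under TGFβ1 against control: in the authors' deposited table FN1, fibronectin, was at 0.78 (implied SE 0.28, limma-adjusted p = 0.296) and COL1A1 at 0.39 (implied SE 0.59, adjusted p = 0.999). With both siRNAs and TGFβ1 against control, G1/S genes fell as a list (median -0.25, 8 lower over all genes, 13 lower and 1 higher adjusted over the list alone), as did interferon-stimulated genes (median -0.21, 5 lower over all genes and 5 adjusted over the list alone), with cameraPR-adjusted p-values of 9.6e-07 and 0.00251, 0.000946 and 0.0487 at a fixed correlation of 0.05, and 0.121 and 0.427, calls lost, at 0.2. The 28S RNA control probe ran from 10.8 to 11.6 in the 5 arrays of replicate 2 and from 11.7 to 12.5 in the other 10 arrays.

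The beta-actin control probe sets fell under both siRNAs: 13.86 ± 0.17 to 13.29 ± 0.09 (SD, n = 3) at the 3′ end, 13.62 ± 0.23 to 12.78 ± 0.23 at the 5′ end and 13.68 ± 0.31 to 12.79 ± 0.24 in the middle, with limma-adjusted p-values of 0.0185, 0.0185 and 0.0439 (0.0067, 0.00466 and 0.0067 with the replicate block). A difference in overall level was argued against by the array medians, which averaged 6.193 ± 0.193 (SD, n = 3) with non-targeting siRNA and 6.197 ± 0.068 with both. With group medians so close, median centring could barely move the falls and adds no further test. After it they were -0.57, -0.85 and -0.89, as large as before. The spread widened, and the limma-adjusted p-values rose to 0.103, 0.0673 and 0.103. RNA degradation stays open, because its measures disagree: the GAPDH 3′ minus 5′ difference was -0.003 between the same groups, while that of beta-actin was higher under both siRNAs (0.518 ± 0.136, SD, n = 3, against 0.238 ± 0.082), as degradation would give. Lower beta-actin RNA in the cells may also account for the falls: the 6 ACTB probe sets of the authors' deposited table, which are not all controls, ran from -0.89 to -0.48 (gene mean -0.72, implied SE 0.14, adjusted p = 0.0239). ACTG1 was at -0.86 (implied SE 0.28, adjusted p = 0.209), so actin may be a poor reference gene for the double knockdown, which is a hypothesis.

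A general reversal of the TGFβ1 response by both siRNAs remains open. Both changes share the non-targeting arrays, which alone gives a negative covariance across probe sets, so the covariance was taken on replicates that share no array. It averaged 0.0143 over 6 pairs of replicates and ran from -0.0371 to 0.1148, with 2 of 6 above 0. Those 2 (0.1148 and 0.0657) took the TGFβ1 change from replicate 1, and the 4 pairs that took it from replicate 2 or 3 ran from -0.0371 to -0.0129, so the sign of the mean rests on replicate 1. By the rule set beforehand a reversal needed all 6 below 0 and its absence all 6 above 0, and the 6 pairs met neither. Without a reversal, values of both signs around 0 would arise, so the rule could not show absence and decides nothing here. Over all arrays the covariance for both siRNAs was -0.0104. Shared arrays alone would give -0.0368, or -0.0211 with the replicate block. That comparison shows no reversal beyond the sharing, but it too holds the replicate 1 arrays.

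For counts of probe sets in comparisons of 3 arrays against 3, the 10 splits of the 6 arrays are too few for a share under 0.05. The real count and the highest other were 143 and 0 under TGFβ1, 2 and 0 under TAZ siRNA, 10 and 3 under YAP siRNA, 90 and 0 under both, 5 and 0 for both against TAZ siRNA, 2 and 0 against YAP siRNA, 13 and 0 for YAP siRNA against TAZ siRNA, and 1729 and 0 for both against control; in each, 1 of the 10 splits, the real one, gave as many. For the study's threshold they were 793 and 703 (1 of 10 as many), 95 and 1340 (6 of 10), 36 and 1186 (7 of 10) and 1042 and 1256 (2 of 10) under TGFβ1, TAZ siRNA, YAP siRNA and both. The splits with the highest other values under TAZ siRNA, YAP siRNA and both put the replicate 1 arrays of both groups on the same side, which points to a structure of the samples by replicate number; the real groups passed 199, 45 and 1356 with the replicate block. Splits that part all 3 pairs, as the real one does, gave at most 250, 21, 20 and 139. With the block, the 4 splits that part all pairs gave 0 in all but the real one.

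Of 100 draws of the 9 arrays into 3 groups, 3, the real one included, gave as many raised probe sets lowered by both siRNAs as the real 2, with a highest other of 58. Those draws ignore the pairing by replicate number. Of 100 draws within replicate numbers 8 gave as many, with a highest other of 58, and with the replicate block 8 of 100 gave as many as the real 75, with a highest other of 890. Draws that exchange whole groups, in all or most replicates, were not left out, and such draws carry real differences between groups. The draws therefore cannot decide on chance, which is not excluded for that count. The count also ran from 0 to 11 when arrays were left out (0 without control or non-targeting replicate 1 or 3). For TAZ siRNA the real value was 0 and the highest other 162, and for YAP siRNA 0 and 0; with a real value of 0 all draws give as many (100 of 100 in each), so they say nothing about chance.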
